A study of Mus musculus with 30 samples.

How the data were processed

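RNA was sequenced from mouse embryonic stem cells and embryoid bodies of 5 lines at 3 time points, with 2 libraries in each of 15 groups, 30 in all. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-marked libraries. The authors deposited 1 table of normalised counts per gene and library, a signal that is never negative and need not be whole. The submitters' processing notes name kallisto 0.43.1, HISAT2 2.0.5, DESeq2 and the mm10 build, without saying which tool made which value. The annotation and the way transcripts were combined into genes are not given in the sources used here.

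The deposited signal was used as it stands. Column totals ran from 15470082 to 18336791. The value of 1 read, read from the steps between low values, puts the depth at an estimated 13198297 to 28151943 reads per library. Between 81.9 and 86.1% of low values, those under 8 steps, were whole multiples of that step within 0.001 of a step. Whole reads were therefore not recovered for nearly all genes, and no count model was run. Each library had 12142 to 13390 genes at a value of 10 or more. Of 20563 symbols, 20361 matched current symbols and 177 matched synonyms in the reference tables, and 25 matched neither. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names.

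Some exact values of 0 can be failed estimates. Rps21 and Rps29, ribosomal protein genes that every cell uses, lay near 0 in every library, and Ezh2 was listed at 0 in 23 of 30 libraries, with a highest value of 82.7. In 2713 of 141010 gene and group pairs (1.92%) in which at least 1 duplicate reached 100, the duplicates differed by more than 8-fold. These pairs belonged to 1168 genes. Genes listed at 0 in a whole group are therefore given as values per library, with no fold.

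Libraries were grouped by title. The descriptions of 2 libraries, replicate 1 of the double knockout at day 0 and at day 4, name the other culture state than their titles, and titles, source names and growth protocols were followed. The labels call the libraries biological duplicates. Whether different clones of a genotype were used is not given in the sources used here, so p-values measure the spread between cultures and not between clones. Pali wild type served as the control of both Pali mutants. C129 wild type served as the control of the Aebp2 gene trap, a pairing read from the order of the series design and not stated in it.

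Before the data were examined, 25 contrasts, 25 gene lists, the test, the naming rule and the alternatives were fixed. Genes with a value of at least 10 in at least 2 libraries were tested, 15712 in all. Values were transformed as log2(value + 4), so fold changes understate the change of low genes. A linear model with 1 mean per group was fitted to all 30 libraries with limma 3.58.1 in R 4.3.3, leaving 15 residual degrees of freedom, with variance moderation by trend and robust estimation. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. All adjusted p-values of single genes are from this limma test. Values are given as mean ± SD of 2 libraries, and SE is that of the log2 fold change.

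Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. Beside the fixed lists, genes that rose or fell at least 2-fold from day 0 to day 8 in the other wild type line were tested as lists. The 234 list tests of the 9 contrasts of a mutant with its wild type were adjusted together. With the preset correlation 78 were called, 45 towards higher and 33 towards lower values. With an estimated correlation none passed, and 39 had an unadjusted p under 0.05. The 396 list tests of the other contrasts were adjusted together as well, with 137 called with the preset correlation and 0 with an estimated one, where 63 had an unadjusted p under 0.05. The list of mitochondrially encoded RNA had 0 of its 15 genes in the table and was not tested.

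Named genes are Lcor, Lcorl and Aebp2, the 5 largest rises and 5 largest falls of each mutant contrast (3 and 3 elsewhere) among called genes with a mean of at least 50 and no overlap between groups, and up to 3 called members of each list per direction with the lowest adjusted p. Pou5f1, Nanog, Zfp42, Fgf5, T, Sox17, Afp, Pax6, Hoxb1 and Hoxa5 were fixed for the course of differentiation. Unnamed models, such as symbols ending in Rik, were passed over among the largest changes.

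The test was run on simulated data made from the real gene means and residual spread, for the double knockout against Pali wild type at day 8, over 15712 genes. The genes given a change were drawn only from those with a mean of at least 50, so recovery among lower genes was not measured. Of 100 genes changed 2-fold, 53 were recovered, and of 100 changed 4-fold, 85 were recovered, with 10 false calls (6.76% of calls). The simulated errors were normal on the log2 scale and held no failed estimates of the kind described above. The share of false calls in the real data may therefore differ.

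Alternatives were pseudocounts of 1 and 16, no filter, a filter at a mean of 50, TMM factors computed from the deposited values (trimming 30% of ratios and 5% of levels), upper-quartile scaling, libraries of the same parent only (18 or 12), the replicate number as a block, limma without trend and robust estimation but with array weights, and leaving out each library in turn. One alternative was chosen after seeing the data, which leaves out the genes with discordant duplicates. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.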

Results

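Mouse embryonic stem cells were compared in culture at day 0 and as embryoid bodies, aggregates that differentiate without the cytokine LIF, at day 4 and day 8. The lines were Pali wild type, a Pali1 knockout, a Pali1/2 double knockout, C129 wild type and an Aebp2 gene trap, with 2 libraries per line and time point. PALI1 and PALI2 are made from the Lcor and Lcorl loci and, like AEBP2, are partners of Polycomb repressive complex 2, which methylates histone H3 at silent developmental genes. The comparisons address what loss of each partner does to expression before and during differentiation. Column totals ran from 15470082 to 18336791 normalised counts. Duplicates correlated at 0.948 to 0.961 across genes (Pearson, log2 scale), where genes are not independent replicates.

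**Figure D1:**
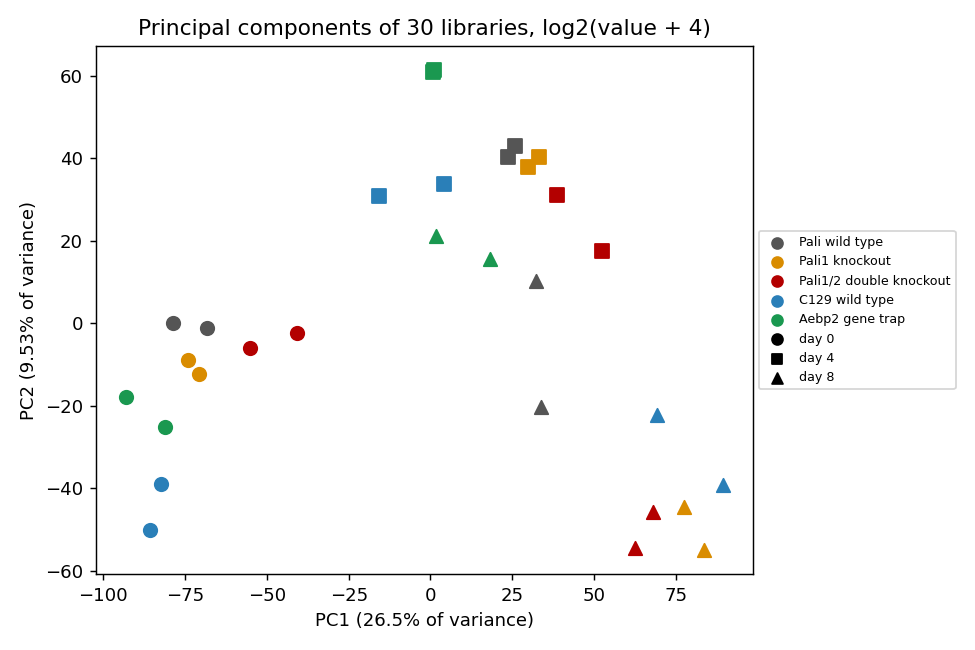
Principal components of the 30 libraries on the log2(value + 4) scale, with colours for lines and symbols for days. PC1 holds 26.5% and PC2 9.5% of the variance.

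Aebp2 (chromosome 6, 140622663 to 140678472, plus strand, GRCm38) lay between 1232 and 2784 normalised counts in the 24 libraries without the trap and between 17.1 and 66.4 in the 6 gene trap libraries. In the trap it fell by 6.20 on the log2 scale at day 0 (SE 0.329, adjusted p = 3.55e-09), by 5.56 at day 4 and by 5.59 at day 8. Lcor (chromosome 19, 41482637 to 41562261, plus strand) lay between 41.4 and 133 and Lcorl (chromosome 5, 45697181 to 45857615, minus strand) between 294 and 858 over the 30 libraries, with no call in either Pali mutant. A gene value does not separate the PALI transcripts from the other transcripts of these loci, so it checks nothing about the deleted part.

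**Figure D2:**
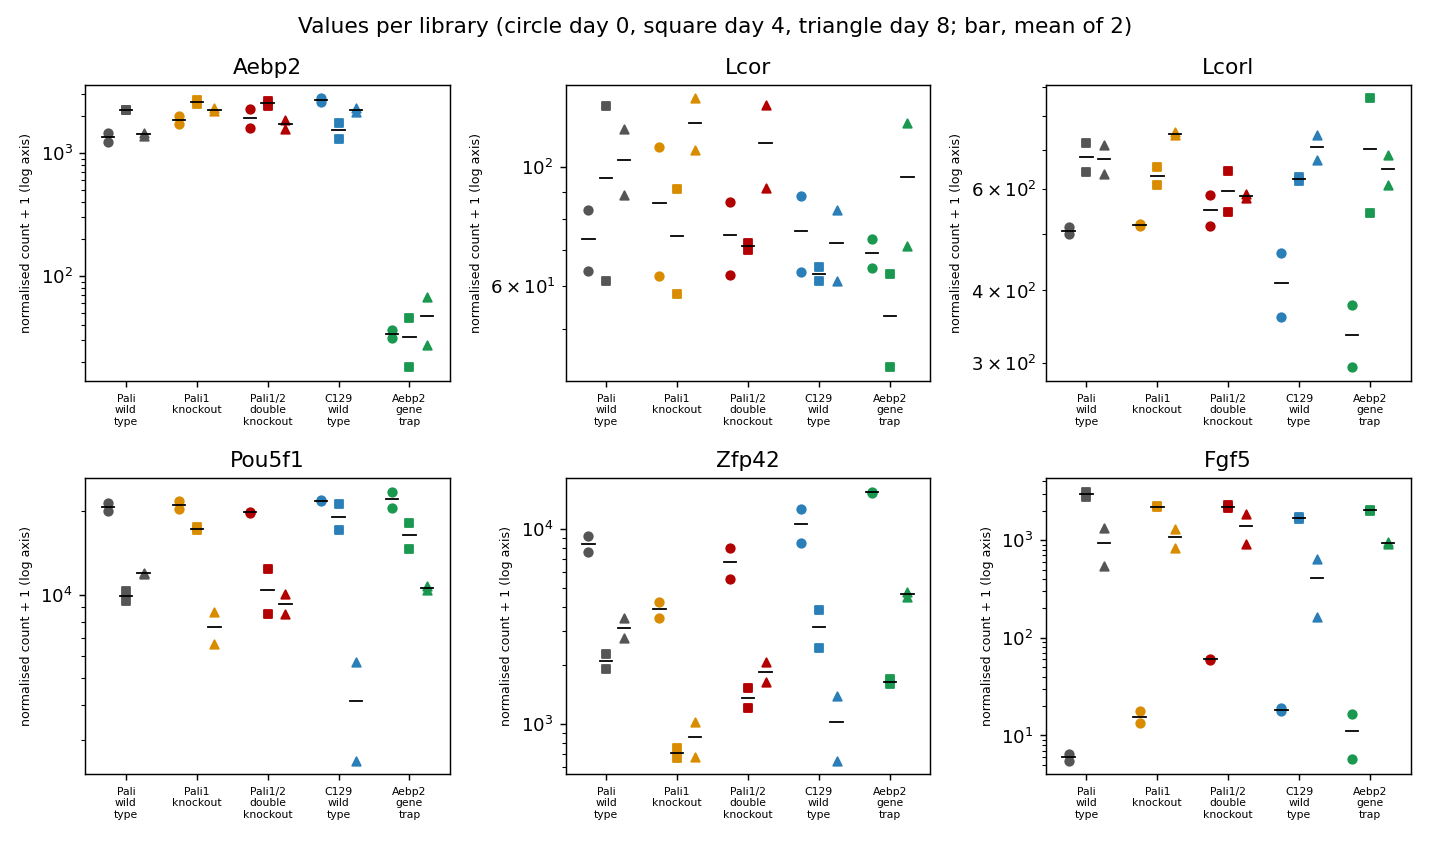
Normalised counts plus 1 on a log axis for 6 genes in each of the 30 libraries, with bars at the mean of 2. Aebp2 lies at 17.1 to 66.4 in the gene trap libraries and at 1232 or more in the others.

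The wild type lines give the course of differentiation. In Pali wild type, Fgf5, a marker of the primed epiblast, rose from 5.01 ± 0.698 at day 0 to 2946 ± 275 at day 4 (SD, n = 2, adjusted p = 4.96e-09). Zfp42, a marker of naive cells, fell from 8406 ± 1078 to 2098 ± 252 at day 4 (adjusted p = 0.000105). Of 29 tested pluripotency genes, 23 fell at day 4 and 18 at day 8, with 0 rises, medians of -1.40 and -0.79 and adjusted p = 8.25e-15 and 7.59e-10. Adjusted over the list alone, 24 and 21 fell and 1 rose at each day, and with an estimated correlation adjusted p = 0.147 and adjusted p = 0.249. The list mean on the log2 scale was higher at day 8 (10.942 and 10.675) than at day 4 (10.282 and 10.274), so the fall did not go on. At day 8, 23 of 66 classical Polycomb target regulators rose and 3 fell (25 and 3 adjusted over the list alone), with a median of 1.23 and adjusted p = 4.31e-06, or adjusted p = 0.147 with an estimated correlation. In all, 4296 genes changed at day 4 (2302 higher, 1994 lower) and 4048 at day 8 (2207 higher, 1841 lower). With TMM rescaling the balance turned to 2131 and 2139 at day 4 and to 2049 and 2083 at day 8.

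In C129 wild type, Pou5f1, the core pluripotency factor, fell by day 8 from 21798 ± 181 to 4134 ± 2274 (adjusted p = 3.49e-07), and Nanog from 15982 ± 1922 to 3900 ± 781. Of 29 pluripotency genes 25 fell and 1 rose, the same numbers adjusted over the list alone, with a median of -2.77 and adjusted p = 8.25e-15, or adjusted p = 0.147 with an estimated correlation. Sox17, an endoderm factor, rose by 4.28 on the log2 scale (SE 0.896, adjusted p = 0.000723) to 247 ± 0.850. At day 4 Pou5f1 was 19121 ± 2857 and was not called. Changed genes numbered 4565 at day 4 (2205 higher, 2360 lower) and 7189 at day 8 (3671 higher, 3518 lower). With TMM rescaling the balance turned to 2261 and 2209 at day 4 and to 3541 and 3550 at day 8. T and Hoxb1 were called in neither line.

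Undifferentiated cells of the Pali1 knockout line had more RNA of 2-cell-like genes, a set active in the early embryo and in rare stem cells. Of 17 tested members 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.97 and adjusted p = 4.46e-13, or adjusted p = 0.0906 with an estimated correlation. Zscan4c rose from 28.6 ± 7.90 to 383 ± 194 (SD, n = 2, adjusted p = 0.00112), and Zscan4a and Zscan4b rose with it. Zscan4 genes are near-identical copies, so the split of reads between them is uncertain. Their sum at day 0 was 736.5 and 1479.8 in the knockout and 104.12 and 59.826 in Pali wild type. It was 39954 and 28811 in C129 wild type, so the wild type lines differed more than the knockout did from its control. The list was also higher at day 4, where 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.93 and adjusted p = 2.48e-07, or adjusted p = 0.193 with an estimated correlation. At day 8, 6 rose and 0 fell, the same numbers adjusted over the list alone, with a median of 0.94 and adjusted p = 0.00169, or adjusted p = 0.395 with an estimated correlation. Otx2, a regulator of the primed state, rose from 150 ± 43.2 to 481 ± 74.2 (adjusted p = 0.000592). Tmsb4x was listed at 0 in both knockout libraries and at 1780 and 2395 in Pali wild type. It was also at 0 in C129 wild type at day 0 and 4, so its values of 0 can be failed estimates. Of 752 changed genes, 477 were higher and 275 lower. Without Pali wild type replicate 1 or 2 the count was 491 or 333, and without knockout replicate 1 or 2 it was 315 or 380.

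At day 4 the knockout had less RNA of pluripotency genes. Of 29 members 8 fell and 0 rose (12 and 1 adjusted over the list alone), with a median of -0.22 and adjusted p = 1.96e-05, or adjusted p = 0.395 with an estimated correlation. The median was -0.37 or -0.41 without Pali wild type replicate 1 or 2. Tdh, a threonine dehydrogenase abundant in naive cells, fell from 6986 ± 386 to 2212 ± 320 (adjusted p = 7.47e-06). The imprinted gene Peg10 fell from 8881 ± 516 to 2398 ± 108 (adjusted p = 8.81e-05), while Meg3, a maternally expressed noncoding RNA, rose from 2586 ± 352 to 5816 ± 449 (adjusted p = 0.00156). Of 32 imprinted genes 7 rose and 2 fell (11 and 4 adjusted over the list alone), with a median of 0.24 and adjusted p = 0.0397, or adjusted p = 0.446 with an estimated correlation. That list call was lost without Pali wild type replicate 2 (adjusted p = 0.171) or knockout replicate 1 (median of 0.0088, adjusted p = 0.207), and its median was 0.46 without knockout replicate 2. It was also lost with upper-quartile rescaling (adjusted p = 0.0516) and without genes with discordant duplicates (median of 0.16, adjusted p = 0.076). Lrp2 fell from 28146 ± 3050 to 9846 ± 2614 (adjusted p = 0.000223). Of 420 changed genes, 168 were higher and 252 lower. The count was 184 without Pali wild type replicate 1, 150 without knockout replicate 1 and 157 without knockout replicate 2.

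At day 8 the Pali1 knockout had less RNA of pluripotency genes and more of neural and mesodermal regulators. Of 29 pluripotency genes 16 fell and 0 rose (21 and 1 adjusted over the list alone), with a median of -0.94 and adjusted p = 1.27e-12, or adjusted p = 0.193 with an estimated correlation. In Pali wild type the list mean on the log2 scale went up from 10.282 and 10.274 at day 4 to 10.942 and 10.675 at day 8. In the knockout it was 9.7774 and 9.9559 at day 4 and 10.194 and 9.8354 at day 8. Part of the day 8 difference thus lies in a rise of the control. Dppa5a fell from 12338 ± 1339 to 4335 ± 248 (adjusted p = 1.11e-05). Of 29 neuroectoderm genes 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 1.12 and adjusted p = 2.92e-06, or adjusted p = 0.204 with an estimated correlation. En1, a midbrain regulator, rose from 34.2 ± 2.76 to 835 ± 161 (adjusted p = 9.89e-05) and En2 from 54.2 ± 17.0 to 933 ± 209. Of 66 Polycomb target regulators 16 rose and 2 fell (20 and 4 adjusted over the list alone), with a median of 0.62 and adjusted p = 0.0105, or adjusted p = 0.395 with an estimated correlation. Wnt1, a signalling ligand of the dorsal neural tube, rose from 28.3 ± 19.6 to 952 ± 287 (adjusted p = 2.74e-06). Of 27 mesoderm genes 11 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 1.18 and adjusted p = 0.000844, or adjusted p = 0.193 with an estimated correlation, and Gsc rose from 25.3 ± 13.8 to 173 ± 43.2. The mesoderm call was lost with the filter at a mean of 50 (median of 1.13, adjusted p = 0.167).

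Hypoxia and glycolysis genes were lower in the Pali1 knockout at day 8. Of 26 members 8 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.56 and adjusted p = 3.79e-06, or adjusted p = 0.351 with an estimated correlation. Egln3, an oxygen-sensing hydroxylase, fell from 829 ± 32.9 to 208 ± 2.56 (adjusted p = 0.000304). Of 32 imprinted genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.68 and adjusted p = 0.000242, or adjusted p = 0.204 with an estimated correlation. Of 2135 changed genes, 1111 were higher and 1024 lower, a balance that turned to 980 and 1117 with TMM rescaling and to 1002 and 1178 with upper-quartile rescaling. The count was 1167 without Pali wild type replicate 2, a library with 1947 normalised counts of the yolk sac gene Afp against 8.03 in replicate 1, and 946 without knockout replicate 2.

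The double knockout already differed at day 0 in several lineage genes. Of 19 fibroblast and mesenchyme genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.29 and adjusted p = 7.04e-10, or adjusted p = 0.0906 with an estimated correlation. Acta2, smooth muscle actin, rose from 9.21 ± 0.931 to 257 ± 9.99 (adjusted p = 0.000262). Of 21 trophoblast genes 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.66 and adjusted p = 2.05e-05, or adjusted p = 0.172 with an estimated correlation. The trophoblast median was 0.41 without Pali wild type replicate 2 and 0.18 without double knockout replicate 1. The keratins Krt8, Krt18 and Krt19, which many epithelia express, were among them. Of 17 2-cell-like genes 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 2.25 and adjusted p = 5.38e-14, or adjusted p = 0.0906 with an estimated correlation, and Zscan4c rose to 490 ± 143. At day 4, 3 of the 17 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.86 and adjusted p = 2.77e-05, or adjusted p = 0.246 with an estimated correlation. At day 8, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.25 and adjusted p = 5.04e-07, or adjusted p = 0.204 with an estimated correlation. Of 20 p53 targets 5 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.33 and adjusted p = 6.58e-07, or adjusted p = 0.0906 with an estimated correlation.

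Of 29 pluripotency genes 3 fell and 1 rose in the double knockout at day 0 (7 and 1 adjusted over the list alone), with a median of -0.33 and adjusted p = 0.000262, or adjusted p = 0.446 with an estimated correlation. The median was -0.22 without Pali wild type replicate 2 and -0.17 without double knockout replicate 2. Tfcp2l1, a naive pluripotency factor, fell from 17357 ± 299 to 5405 ± 75.8 (adjusted p = 0.000897), and the imprinted growth factor gene Igf2 rose from 27.0 ± 8.79 to 216 ± 53.8 (adjusted p = 0.000262). Of 577 changed genes, 464 were higher and 113 lower. The count was 301 without Pali wild type replicate 1, 260 without double knockout replicate 1, whose description names the other culture state, and 340 without double knockout replicate 2.

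At day 4, 6 of 29 pluripotency genes fell in the double knockout and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.59 and adjusted p = 6.39e-11, or adjusted p = 0.204 with an estimated correlation. Tdh fell from 6986 ± 386 to 2335 ± 181 (adjusted p = 1.95e-05) and Esrrb, a naive pluripotency factor, from 4140 ± 18.6 to 1519 ± 682. Of 29 neuroectoderm genes 1 rose and 1, Olig1, fell (5 and 2 adjusted over the list alone), and the list was called towards higher values with a median of 0.68 and adjusted p = 0.00848, or adjusted p = 0.446 with an estimated correlation. The call was lost without double knockout replicate 2 (median of 0.51, adjusted p = 0.138). Olig1, a neural progenitor factor, was 104 ± 23.1 in the double knockout against 405 ± 93.3 (adjusted p = 0.00113). Peg13, an imprinted noncoding RNA, rose from 12.3 ± 1.85 to 148 ± 26.4 (adjusted p = 0.00196). Of 325 changed genes, 155 were higher and 170 lower, against 158 and 153 with upper-quartile rescaling. The count was 80 without Pali wild type replicate 1, 157 without double knockout replicate 1 and 154 without replicate 2.

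At day 8 the double knockout had less RNA of pluripotency genes and more of neural, mesodermal and Polycomb target genes. Of 29 pluripotency genes 11 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.59 and adjusted p = 2.68e-11, or adjusted p = 0.204 with an estimated correlation. The list mean on the log2 scale went up from day 4 to day 8 here too, from 9.6885 and 9.7087 to 10.271 and 10.117. Of 29 neuroectoderm genes 10 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 1.36 and adjusted p = 6.58e-07, or adjusted p = 0.193 with an estimated correlation. Fabp7, a radial glia gene, rose by 3.04 on the log2 scale (SE 0.492, adjusted p = 0.00158) to 670 ± 167. Of 66 Polycomb target regulators 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.63 and adjusted p = 0.000299, or adjusted p = 0.242 with an estimated correlation. Zic4 was listed at 0 in both Pali wild type libraries and at 139 and 195 in the double knockout. Of 27 mesoderm genes 9 rose and 0 fell, the same numbers adjusted over the list alone, with a median of 0.98 and adjusted p = 1.37e-05, or adjusted p = 0.0906 with an estimated correlation, and the median was 1.51 without double knockout replicate 1.

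Of 1133 genes changed in the double knockout at day 8, 649 were higher and 484 lower, against 432 and 457 with the filter at a mean of 50. The count was 338 without Pali wild type replicate 2, the library with high Afp, and 308 or 411 without double knockout replicate 1 or 2. The list of extraembryonic endoderm genes was lower with 2 of 29 genes falling and 1 rising (4 and 1 adjusted over the list alone), a median of -0.41 and adjusted p = 0.0367, or adjusted p = 0.704 with an estimated correlation. Its median was -0.996 without Pali wild type replicate 1, turned to 0.37 without replicate 2 (adjusted p = 0.441) and was -0.38 without double knockout replicate 1 (adjusted p = 0.283), and Afp is among the 2. The call was also lost with the filter at a mean of 50 (median of -0.24, adjusted p = 0.424), TMM rescaling (adjusted p = 0.0506), upper-quartile rescaling (adjusted p = 0.0547), libraries of the same parent only (adjusted p = 0.0899) and without genes with discordant duplicates (median of 0.083, adjusted p = 0.59).

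Markers of other cell types and several other lists were also called in the Pali mutants. Of 19 fibroblast and mesenchyme genes 4 were higher and 0 lower in the Pali1 knockout at day 0 (5 and 0 adjusted over the list alone), with a median of 0.85 and adjusted p = 0.00179, or adjusted p = 0.395 with an estimated correlation. The fibroblast median there was 0.37 without Pali wild type replicate 1. Of 19 fibroblast and mesenchyme genes 3 were higher and 0 lower in the Pali1 knockout at day 8 (the same numbers adjusted over the list alone), with a median of 0.78 and adjusted p = 0.0264, or adjusted p = 0.518 with an estimated correlation. The fibroblast call there was lost without genes with discordant duplicates (adjusted p = 0.0609) and without Pali wild type replicate 1 (adjusted p = 0.0873). Of 19 fibroblast and mesenchyme genes 2 were higher and 0 lower in the double knockout at day 4 (6 and 1 adjusted over the list alone), with a median of 0.54 and adjusted p = 0.000636, or adjusted p = 0.351 with an estimated correlation. Of 21 trophoblast genes 4 were higher and 0 lower in the Pali1 knockout at day 0 (6 and 0 adjusted over the list alone), with a median of 0.31 and adjusted p = 0.00634, or adjusted p = 0.351 with an estimated correlation. The trophoblast call there was lost without Pali wild type replicate 2 (adjusted p = 0.0554). The trophoblast median there was 0.50 without Pali wild type replicate 1, 0.48 without knockout replicate 1 and 0.15 without knockout replicate 2. Of 20 p53 targets 2 were higher and 0 lower in the Pali1 knockout at day 0 (3 and 0 adjusted over the list alone), with a median of 0.22 and adjusted p = 0.00348, or adjusted p = 0.227 with an estimated correlation. Of 25 germline genes 3 were lower and 1 higher in the Pali1 knockout at day 8 (4 and 1 adjusted over the list alone), with a median of -0.68 and adjusted p = 0.0202, or adjusted p = 0.396 with an estimated correlation. The germline call there was lost without Pali wild type replicate 1 (adjusted p = 0.107) and without knockout replicate 2 (adjusted p = 0.111). Of 26 hypoxia and glycolysis genes 3 were lower and 0 higher in the double knockout at day 8 (6 and 0 adjusted over the list alone), with a median of -0.39 and adjusted p = 0.000216, or adjusted p = 0.444 with an estimated correlation.

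In the double knockout, neural, Polycomb target and imprinted genes were also called at earlier days. Of 29 neuroectoderm genes 2 were higher and 0 lower in the double knockout at day 0 (3 and 0 adjusted over the list alone), with a median of 0.23 and adjusted p = 0.0365, or adjusted p = 0.534 with an estimated correlation. The neuroectoderm call there was lost with a pseudocount of 16 (adjusted p = 0.0952), with libraries of the same parent only (adjusted p = 0.0739), without Pali wild type replicate 1 (median of 0.096, adjusted p = 0.229) and without double knockout replicate 2 (median of 0.10, adjusted p = 0.332). The neuroectoderm median there was 0.42 without Pali wild type replicate 2 and 0.67 without double knockout replicate 1. Of 66 Polycomb target regulators 1 was higher and 0 lower in the double knockout at day 4 (4 and 0 adjusted over the list alone), with a median of 0.33 and adjusted p = 0.0332, or adjusted p = 0.446 with an estimated correlation. The Polycomb call there was lost without Pali wild type replicate 1 (adjusted p = 0.128) and without double knockout replicate 2 (median of 0, adjusted p = 0.525). The Polycomb median there was 0.53 without double knockout replicate 1. Of 32 imprinted genes 5 were higher and 1 lower in the double knockout at day 0 (8 and 1 adjusted over the list alone), with a median of 0.34 and adjusted p = 0.0149, or adjusted p = 0.395 with an estimated correlation. The imprinted call there was lost without Pali wild type replicate 1 (adjusted p = 0.0643) and without double knockout replicate 2 (median of 0.19, adjusted p = 0.148). Of 32 imprinted genes 3 were higher and 3 lower in the double knockout at day 4 (7 and 3 adjusted over the list alone), with a median of 0.30 and adjusted p = 0.0488, or adjusted p = 0.446 with an estimated correlation. The imprinted call there was lost with a pseudocount of 1 (adjusted p = 0.0544), with upper-quartile rescaling (adjusted p = 0.0549), without genes with discordant duplicates (adjusted p = 0.0916), without Pali wild type replicate 2 (adjusted p = 0.216) and without double knockout replicate 2 (median of 0.16, adjusted p = 0.217).

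**Figure D3:**
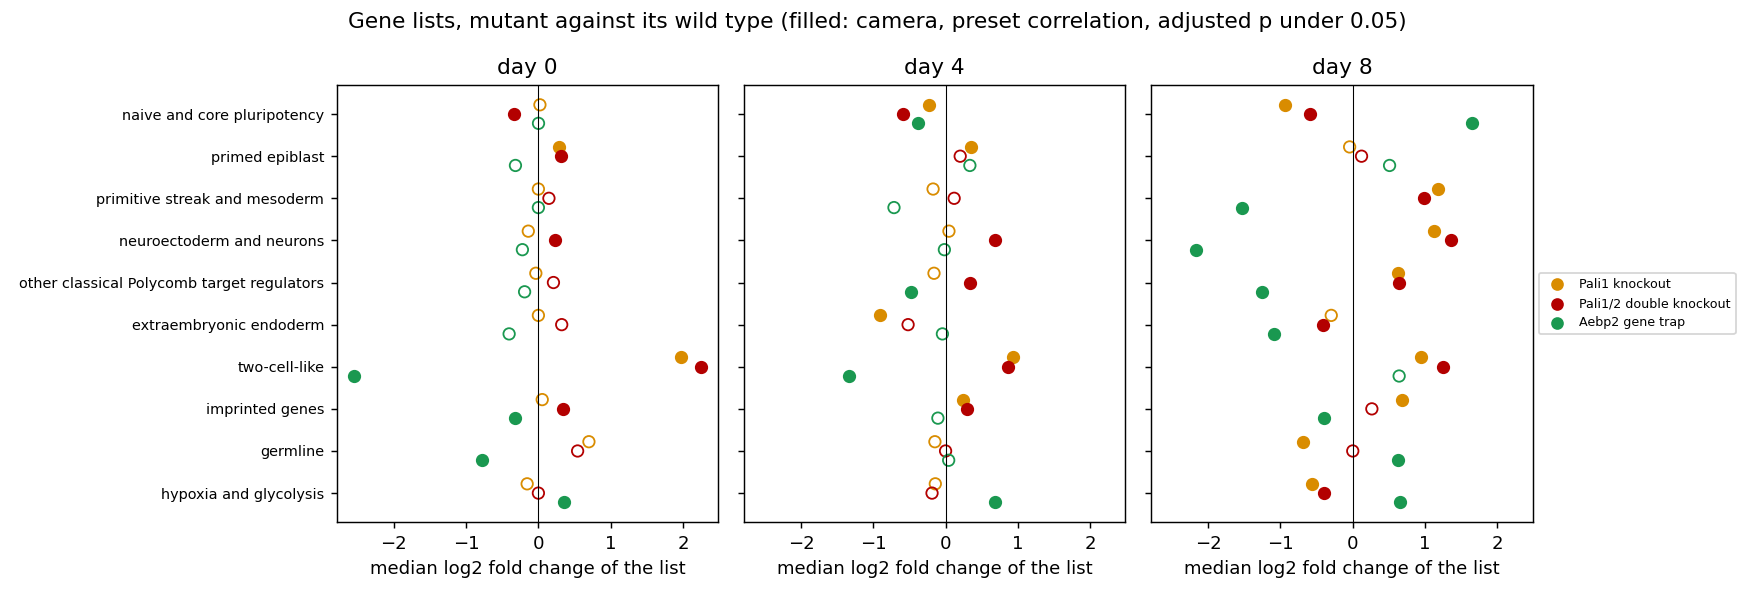
Median log2 fold change of 10 gene lists in each mutant against its wild type at day 0, 4 and 8, with filled points where camera with a preset correlation gave an adjusted p under 0.05. At day 8 the pluripotency median is 1.65 in the Aebp2 gene trap and -0.94 and -0.59 in the Pali mutants.

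In undifferentiated cells, 2-cell-like genes were lower in the Aebp2 gene trap. Of 17 members 14 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -2.55 and adjusted p = 1.22e-10, or adjusted p = 0.0906 with an estimated correlation. At day 4, 7 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -1.34 and adjusted p = 1.09e-05, or adjusted p = 0.242 with an estimated correlation. At day 8 the median was 0.64 and the list was not called (adjusted p = 0.135). Tdpoz4 fell at day 0 from 157 ± 16.1 to 14.7 ± 3.16 (adjusted p = 5.69e-05). H19, an imprinted noncoding RNA, fell from 700 ± 333 to 46.0 ± 35.7 (adjusted p = 8.73e-05), and Hk2, a hexokinase of glycolysis, rose from 3136 ± 470 to 7403 ± 1556 (adjusted p = 0.000826). Tmsb4x was listed at 0 in both C129 wild type libraries and at 1130 and 1902 in the trap. It was also at 0 in the trap at day 4 and in the Pali1 knockout at day 0, so its values of 0 can be failed estimates. Of 2044 changed genes, 821 were higher and 1223 lower (967 and 1096 with TMM rescaling, 862 and 952 with the filter at a mean of 50). With upper-quartile rescaling 38.55% of called genes were higher, against 40.17%. The count was 979 with libraries of the same parent only, 805 without C129 wild type replicate 1 and 1049 without gene trap replicate 2.

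At day 4, 9 of 26 hypoxia and glycolysis genes rose in the trap and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.69 and adjusted p = 1.17e-08, or adjusted p = 0.242 with an estimated correlation. The median was 0.25 without gene trap replicate 1 (adjusted p = 0.007) and 1.06 without its replicate 2, and the list mean on the log2 scale was 10.194 and 9.4319 in the trap against 9.2157 and 8.8224 in C129 wild type. Slc2a1, a glucose transporter, rose from 8507 ± 1046 to 23635 ± 10350 (adjusted p = 0.00241). Of 29 pluripotency genes 7 fell and 2 rose (12 and 3 adjusted over the list alone), with a median of -0.38 and adjusted p = 0.00127, or adjusted p = 0.518 with an estimated correlation, and adjusted p = 0.0837 without C129 wild type replicate 1. Klf2 fell from 2346 ± 476 to 828 ± 10.0 (adjusted p = 0.00031). Of 1416 changed genes, 637 were higher and 779 lower. The count was 395 with libraries of the same parent only, 402 without C129 wild type replicate 1 (207 higher, 195 lower) and 617 without gene trap replicate 1.

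At day 8 the trap had more RNA of pluripotency genes and less of neural, mesodermal and Polycomb target genes. Of 29 pluripotency genes 23 rose and 1, Lin28a, fell (25 and 1 adjusted over the list alone), with a median of 1.65 and adjusted p = 6.8e-19, or adjusted p = 0.0906 with an estimated correlation. Dppa5a rose from 1942 ± 104 to 14798 ± 2010 (adjusted p = 2.44e-09), and Fgf4 from 369 ± 142 to 2666 ± 256 (adjusted p = 8.03e-07). Of 29 neuroectoderm genes 16 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -2.16 and adjusted p = 2.54e-09, or adjusted p = 0.0965 with an estimated correlation. Pax3, a dorsal neural regulator, fell from 531 ± 30.7 to 14.7 ± 0.184 (adjusted p = 1.54e-06). Of 66 Polycomb target regulators 28 fell and 1, Wt1, rose (30 and 1 adjusted over the list alone), with a median of -1.26 and adjusted p = 5.07e-09, or adjusted p = 0.0906 with an estimated correlation. Wnt1 fell from 691 ± 349 to 4.46 ± 1.80 (adjusted p = 1.07e-07) and Irx5 from 394 ± 64.6 to 8.07 ± 0.993 (adjusted p = 8.6e-07).

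Of 27 mesoderm genes 13 fell in the trap at day 8 and 1, Tcf15, rose (17 and 2 adjusted over the list alone). The mesoderm median was -1.53 with adjusted p = 2.77e-05, or adjusted p = 0.0906 with an estimated correlation. With the filter at a mean of 50 the call was lost (adjusted p = 0.122), though the median was -2.05. Germline genes were higher at day 8, with 7 of 25 rising and 0 falling, the same numbers adjusted over the list alone, a median of 0.62 and adjusted p = 0.00475, or adjusted p = 0.337 with an estimated correlation. The germline median was 0.097 without C129 wild type replicate 2 (adjusted p = 0.0487) and 0.98 without its replicate 1. Sycp3, a meiotic chromosome protein, rose from 246 ± 162 to 976 ± 133 (adjusted p = 0.000149). Of 3165 changed genes, 1506 were higher and 1659 lower, a balance that turned to 1607 and 1480 with TMM rescaling. The count was 2023 without C129 wild type replicate 2 and 1682 without gene trap replicate 1.

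Germline genes were lower in the trap at day 0, and imprinted, glycolysis, p53 and Polycomb target genes were also called. Of 25 germline genes 5 were lower and 0 higher in the gene trap at day 0 (6 and 0 adjusted over the list alone), with a median of -0.78 and adjusted p = 0.0185, or adjusted p = 0.395 with an estimated correlation. The germline call there was lost without C129 wild type replicate 1 (median of -0.29, adjusted p = 0.0952). Of 32 imprinted genes 9 were lower and 2 higher in the gene trap at day 0 (10 and 3 adjusted over the list alone), with a median of -0.32 and adjusted p = 0.0436, or adjusted p = 0.446 with an estimated correlation. The imprinted call there was lost with a pseudocount of 16 (adjusted p = 0.0721), with libraries of the same parent only (adjusted p = 0.0747), without genes with discordant duplicates (adjusted p = 0.0673), without C129 wild type replicate 2 (adjusted p = 0.0971), without gene trap replicate 1 (adjusted p = 0.0601) and without gene trap replicate 2 (adjusted p = 0.0504). Of 32 imprinted genes 11 were lower and 1 higher in the gene trap at day 8 (11 and 2 adjusted over the list alone), with a median of -0.40 and adjusted p = 0.005, or adjusted p = 0.337 with an estimated correlation. The imprinted call there was lost without gene trap replicate 1 (adjusted p = 0.061). The imprinted median there was -0.65 without gene trap replicate 2. Of 26 hypoxia and glycolysis genes 3 were higher and 0 lower in the gene trap at day 0 (the same numbers adjusted over the list alone), with a median of 0.36 and adjusted p = 0.0104, or adjusted p = 0.569 with an estimated correlation. The hypoxia call there was lost without gene trap replicate 2 (adjusted p = 0.0504). Of 26 hypoxia and glycolysis genes 8 were higher and 0 lower in the gene trap at day 8 (9 and 0 adjusted over the list alone), with a median of 0.65 and adjusted p = 0.000358, or adjusted p = 0.446 with an estimated correlation. Of 20 p53 targets 5 were lower and 0 higher in the gene trap at day 0 (the same numbers adjusted over the list alone), with a median of -0.23 and adjusted p = 0.00821, or adjusted p = 0.246 with an estimated correlation. The p53 call there was lost without C129 wild type replicate 1 (median of -0.10, adjusted p = 0.0836) and without gene trap replicate 2 (adjusted p = 0.0519). The p53 median there was -0.38 without C129 wild type replicate 2 and -0.35 without gene trap replicate 1. Of 66 Polycomb target regulators 6 were lower and 0 higher in the gene trap at day 4 (the same numbers adjusted over the list alone), with a median of -0.48 and adjusted p = 0.00821, or adjusted p = 0.395 with an estimated correlation. The Polycomb call there was lost with the filter at a mean of 50 (median of -0.55, adjusted p = 0.0762) and without gene trap replicate 2 (median of -0.36).

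The double knockout and the single knockout were compared directly. At day 0 the double knockout had 320 genes higher and 163 lower than the Pali1 knockout, at day 4 146 and 71, and at day 8 147 and 69. Without 1 library the count fell from 483 to 94 (Pali1 knockout replicate 1) or 98 (double knockout replicate 2) at day 0. At day 4 it fell from 217 to 62 or 100 without Pali1 knockout replicate 1 or 2, and to 127 without double knockout replicate 2. At day 8 it fell from 216 to 134 or 119 without Pali1 knockout replicate 1 or 2, and to 110 or 102 without double knockout replicate 1 or 2, and with array weights it was 388. At day 8 Wnt1 was 113.8 and 51.4 in the double knockout libraries and 749 and 1155 in the Pali1 knockout libraries (adjusted p = 0.00027). Their effects against the same Pali wild type libraries correlated across genes at 0.56, 0.54 and 0.61 at day 0, 4 and 8, where unchanged groups simulated against shared controls gave 0.50 at each day. The covariance was 0.348, 0.306 and 0.479 against 0.225, 0.225 and 0.227 simulated. At day 8, 405 genes were higher in both and 361 lower in both, where independent lists give 45.9 and 31.5. Splitting the controls would leave 1 library each, and part of the excess may come from the shared controls.

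Effects of the double knockout and of the Aebp2 gene trap share no libraries. They correlated across genes at -0.18 at day 0, -0.05 at day 4 and -0.30 at day 8. With a library left out the day 4 value ran from -0.0723 (gene trap replicate 2) to -0.0181 (gene trap replicate 1). Of 673 genes called in both at day 8, 349 were higher in the double knockout and lower in the trap and 308 the reverse, which is 97.6%, where independent lists give 68.5 and 46.4. At day 0 the opposite pairs were 177 and 27 of 219 genes (93.2%). At day 4 they were 41 and 12 of 77 genes (68.8%), and 21 genes were lower in both, where independent lists give 8.43. The difference of the effects was past the threshold for 2014 genes at day 0, 953 at day 4 and 3765 at day 8. The day 0 count was 1272 without C129 wild type replicate 1, and the day 4 count was 548 without Pali wild type replicate 1, 617 or 532 without double knockout replicate 1 or 2, 522 without C129 wild type replicate 1 and 463 without gene trap replicate 1. For 29 pluripotency genes the median difference at day 8 was -2.15, with 24 lower and 1 higher (25 and 1 adjusted over the list alone) and adjusted p = 1.23e-18, or adjusted p = 0.12 with an estimated correlation. Most of this difference lies between the wild types, whose pluripotency genes differed by a median of -1.70 (C129 against Pali) at day 8. The list mean on the log2 scale was 10.9 and 10.7 in Pali wild type, 10.3 and 10.1 in the double knockout, 10.8 and 10.6 in the trap and 9.51 and 9.11 in C129 wild type.

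**Figure D4:**
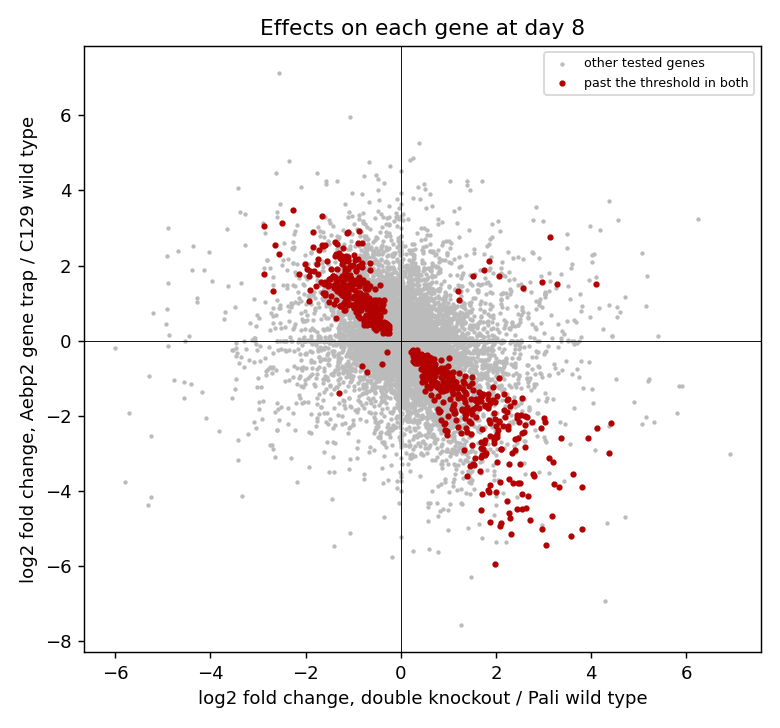
Log2 fold change at day 8 of each of 15712 genes in the double knockout (horizontal) and in the Aebp2 gene trap (vertical), each against its wild type. Of the 673 genes past the threshold in both, 657 lie in the quadrants of opposite sign.

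The wild type lines differed from each other before any mutation. C129 wild type had 1886 genes higher and 1423 lower than Pali wild type at day 0, 1312 and 1190 at day 4, and 1392 and 1334 at day 8. The balance turned with TMM rescaling to 1625 higher and 1657 lower at day 0 and to 1231 and 1403 at day 8, and with the filter at a mean of 50 to 1365 and 1399 at day 0 and 1209 and 1251 at day 8. The counts were 2143, 1446 and 1766 without Pali wild type replicate 1 of that day, and 1830, 1150 and 1442 without C129 wild type replicate 1, 1 and 2. Zscan4c was 11995 ± 3016 in C129 and 28.6 ± 7.90 in Pali wild type at day 0 (adjusted p = 1.05e-08). At day 8, 24 of 29 pluripotency genes were lower in C129 wild type and 1 was higher, the same numbers adjusted over the list alone, with a median of -1.70 and adjusted p = 1.24e-21, or adjusted p = 0.12 with an estimated correlation. The Y-linked gene Eif2s3y lay at 0 in the 18 Pali libraries and at 140.5 or more in the 12 C129 and trap libraries. Line, parent, RNA of this Y-linked gene and any processing batch cannot be told apart between the parents.

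Subunits of Polycomb repressive complexes 1 and 2, Hox genes, blood, cardiac muscle and abundant non-polyadenylated RNA were called in 0 of the 9 mutant contrasts, with lowest adjusted p of 0.235, 0.171, 0.0690, 0.208, 0.108 and 0.105. Only 14 of 39 Hox genes were tested, with low list means of 2.5655 to 4.1571 on the log2 scale. Ezh2, a subunit of complex 2, was listed at 0 in 23 of 30 libraries, so its values cannot show whether it changed. Endoderm, endothelium, sex chromosome and stress response genes were each called in 1. Of 16 endoderm genes 1 was lower and 0 higher in the double knockout at day 4 (the same numbers adjusted over the list alone), with a median of -0.43 and adjusted p = 0.0488, or adjusted p = 0.518 with an estimated correlation. The endoderm call there was lost with a pseudocount of 1 (adjusted p = 0.0611), with TMM rescaling (adjusted p = 0.0514), with the replicate block (adjusted p = 0.0502), with libraries of the same parent only (adjusted p = 0.0614), without genes with discordant duplicates (adjusted p = 0.0731), without Pali wild type replicate 2 (median of 0, adjusted p = 0.847) and without double knockout replicate 1 (median of -0.18, adjusted p = 0.22). The endoderm median there was -0.695 without Pali wild type replicate 1. Of 15 endothelium genes 1 was higher and 0 lower in the double knockout at day 0 (the same numbers adjusted over the list alone), with a median of 0.77 and adjusted p = 0.00885, or adjusted p = 0.242 with an estimated correlation. The endothelium call there was lost without Pali wild type replicate 1 (adjusted p = 0.0532) and without double knockout replicate 2 (median of 0.45, adjusted p = 0.105). Of 5 sex chromosome genes 2 were lower and 0 higher in the Pali1 knockout at day 4 (the same numbers adjusted over the list alone), with a median of -0.25 and adjusted p = 0.0488, or adjusted p = 0.242 with an estimated correlation. The sex chromosome call there was lost with a pseudocount of 1 (adjusted p = 0.0536), with libraries of the same parent only (adjusted p = 0.0686), without genes with discordant duplicates (adjusted p = 0.0531), without Pali wild type replicate 1 (median of 0, adjusted p = 0.158) and without knockout replicate 2 (adjusted p = 0.105). The sex chromosome median there was -0.62 without Pali wild type replicate 2 and -0.14 without knockout replicate 1. Of 23 stress response genes 0 were higher and 0 lower in the double knockout at day 4 (the same numbers adjusted over the list alone), with a median of 0.47 and adjusted p = 0.049, or adjusted p = 0.497 with an estimated correlation. The stress response call there was lost with a pseudocount of 16 (adjusted p = 0.0525), with upper-quartile rescaling (adjusted p = 0.0547), without genes with discordant duplicates (adjusted p = 0.076), without Pali wild type replicate 1 (median of 0.18, adjusted p = 0.415), without double knockout replicate 1 (adjusted p = 0.0597) and without double knockout replicate 2 (adjusted p = 0.145).

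Extraembryonic endoderm genes were called in 3 of the 9 contrasts, with a lowest adjusted p of 6.43e-05 in the Pali1 knockout at day 4 (0 of 29 higher and 1 lower, or 0 and 2 adjusted over the list alone, median of -0.91, adjusted p = 0.446 with an estimated correlation). The median was -1.55 without Pali wild type replicate 1 of day 4, and the call was lost without its replicate 2 (median of -0.16, adjusted p = 0.282), a library whose list mean on the log2 scale was 7.4977 against 5.757 in replicate 1. Of 29 extraembryonic endoderm genes 9 were lower and 1 higher in the gene trap at day 8 (the same numbers adjusted over the list alone), with a median of -1.08 and adjusted p = 0.00238, or adjusted p = 0.542 with an estimated correlation. That call was lost with the filter at a mean of 50 (median of -0.32, adjusted p = 0.064).

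Primed epiblast genes were called in 3 contrasts and proliferation genes in 4. Of 16 primed epiblast genes 2 were higher and 0 lower in the Pali1 knockout at day 0 (the same numbers adjusted over the list alone), with a median of 0.28 and adjusted p = 0.0488, or adjusted p = 0.566 with an estimated correlation. The primed epiblast call there was lost with a pseudocount of 16 (adjusted p = 0.0632), with upper-quartile rescaling (adjusted p = 0.0529), without Pali wild type replicate 1 (median of 0.12, adjusted p = 0.62) and without knockout replicate 2 (adjusted p = 0.51). The primed epiblast median there was 0.54 without Pali wild type replicate 2 and 0.43 without knockout replicate 1. Of 16 primed epiblast genes 0 were higher and 0 lower in the Pali1 knockout at day 4 (3 and 0 adjusted over the list alone), with a median of 0.35 and adjusted p = 0.0101, or adjusted p = 0.463 with an estimated correlation. The primed epiblast call there was lost without Pali wild type replicate 1 (median of 0.15, adjusted p = 0.27) and without knockout replicate 2 (adjusted p = 0.0661). Of 16 primed epiblast genes 6 were higher and 0 lower in the double knockout at day 0 (7 and 1 adjusted over the list alone), with a median of 0.32 and adjusted p = 0.00144, or adjusted p = 0.395 with an estimated correlation. The primed epiblast call there was lost without Pali wild type replicate 1 (median of -0.11, adjusted p = 0.0643). The primed epiblast median there was 0.82 without Pali wild type replicate 2 and 0.67 without double knockout replicate 1. Of 26 proliferation genes 3 were lower and 0 higher in the Pali1 knockout at day 8 (6 and 0 adjusted over the list alone), with a median of -0.16 and adjusted p = 0.000353, or adjusted p = 0.366 with an estimated correlation. Of 26 proliferation genes 0 were lower and 0 higher in the double knockout at day 4 (the same numbers adjusted over the list alone), with a median of -0.15 and adjusted p = 3.89e-05, or adjusted p = 0.265 with an estimated correlation. The proliferation median there was -0.0933 without Pali wild type replicate 2 and -0.0998 without double knockout replicate 2. Of 26 proliferation genes 1 was lower and 0 higher in the double knockout at day 8 (4 and 0 adjusted over the list alone), with a median of -0.12 and adjusted p = 0.000812, or adjusted p = 0.395 with an estimated correlation. Of 26 proliferation genes 4 were higher and 0 lower in the gene trap at day 8 (the same numbers adjusted over the list alone), with a median of 0.09 and adjusted p = 0.034, or adjusted p = 0.548 with an estimated correlation. The proliferation call there was lost with the filter at a mean of 50 (adjusted p = 0.0529), without C129 wild type replicate 1 (adjusted p = 0.0583) and without gene trap replicate 1 (adjusted p = 0.14).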

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

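Of the tests in this part, the comparison of the mutant lines without their wild types and the test on summed Zscan4 values were chosen only after the results they measure were seen. The effect of a mutation at day 8 differed from its effect at day 0, by a test of the difference itself, for 900 genes in the Pali1 knockout, 176 in the double knockout and 2399 in the Aebp2 gene trap. Of the fixed lists and the lists of genes rising or falling in the other wild type, 12, 12 and 8 differed in this way. Of 289 named genes, 54, 26 and 98 did, against 900, 176 and 2399 of all 15712 tested genes. Most named genes were picked as called in a mutant contrast of these same libraries. That favours such a difference in advance, so the counts of named genes add no support. The list calls in this paragraph are those of limma's camera with the preset correlation, and with an estimated correlation 0 of the 396 list tests outside the mutant contrasts passed (63 had an unadjusted p under 0.05). These list calls were not recomputed under the alternatives or with libraries left out. The count of 900 was 272 without Pali wild type replicate 2 of day 0, 448 without its replicate 2 of day 8, 353 without Pali1 knockout replicate 1 of day 0 and 240 without its replicate 2 of day 8. The count of 176 ran from 44 without Pali wild type replicate 2 of day 8 to 304 without its replicate 1. It was 98 without Pali wild type replicate 2 of day 0, 58 or 109 without double knockout replicate 1 or 2 of day 0, and 62 or 74 without replicate 1 or 2 of day 8. The count of 2399 was 1534 without C129 wild type replicate 1 of day 0, 1451 without its replicate 2 of day 8, 1348 without gene trap replicate 1 of day 8, and 1165 with libraries of the same parent only. The effect of the double knockout differed from that of the trap for 2014 genes at day 0, 953 at day 4 and 3765 at day 8. With them came 10, 6 and 8 fixed lists and 102, 67 and 154 named genes. The limit on the named genes given above holds here too.

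At day 8 the Pali mutants and the Aebp2 gene trap moved in opposite directions on pluripotency genes and on Polycomb target regulators, by list calls with the preset correlation that were all lost with an estimated one (lowest adjusted p = 0.0906). A plain shift along the course of differentiation was tested by matching each of 66 regulators to genes with a like change in the other wild type line. The list medians of 0.62, 0.63 and -1.26 in the Pali1 knockout, the double knockout and the trap lay at percentiles 99.41, 99.93 and 0 of 10000 such lists. The central 95% of those lists ran from 0.11 to 0.53, 0.033 to 0.45 and -0.62 to -0.028. Those lists were drawn gene by gene and ignore correlation between the regulators. Their spread may be too narrow, so the percentiles cannot decide on such a shift. Rescaling left at least 1.015 times the median difference on pluripotency genes. It moved the median difference over all genes only from 0.0544 to 0 with TMM and to 0.024 with the upper quartile. Rescaling by so little could not have removed a difference of -2.15, and other steps of the deposited normalisation were not tested. The double knockout libraries still lay 0.52 below the trap libraries (-0.52 on the log2 scale, median) with no wild type in the comparison. That is a small part of the difference of -2.15 between the effects on pluripotency genes. Their list means in the double knockout lay between those of the wild types and in the trap overlapped those of Pali wild type. The gap between the wild types may thus account for most of the opposition there. On Polycomb target regulators the day 8 list means of the Pali mutant libraries were 5.3783 to 5.5985 on the log2 scale. These overlapped those of C129 wild type, 5.3488 and 5.5907. Those of the trap, 3.8145 and 3.9783, lay below all 4 wild type libraries of day 8. They lay near C129 wild type at day 0, 3.9047 and 3.9691, which a shift along the course would allow. Clone and parent remain untested.

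In undifferentiated cells and at day 4, 2-cell-like genes were higher in both Pali mutants and lower in the trap, whereas at day 8 they were higher in both Pali mutants and not called in the trap (median of 0.64, adjusted p = 0.135), by list calls that were all lost with an estimated correlation (lowest adjusted p = 0.0906), and the tests here cover day 0. Reads split between near-identical Zscan4 copies would leave their sum unchanged. The sum over 5 Zscan4 genes differed by 3.66, 4.06 and -2.48 on the log2 scale, at least 2.477 in size. This sum was chosen after the called members of the list were seen to move in the same direction. Its direction was thus largely given in advance, and it adds no independent support. Fluctuation between cultures gave at most 1.003 between duplicates. The sums were 104 and 59.8 in Pali wild type, 39954 and 28811 in C129 wild type, and 6718 and 5520 in the trap, so the wild types differed by more than any mutant did. A difference between clones of a line, which 1 line per genotype cannot separate from the mutation, may be the source and stays open.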

How the results depend on the processing

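The test without discordant genes was chosen after seeing the data. Over 12 settings other than leaving out a library, 265 of 276 counts and correlations stayed within 1.5 times or within their spread. Over all genes, the filter at a mean of 50 kept 68.06 to 90.48% of the main calls per contrast. Named genes were mostly picked as called in the main fit, so keeping the call was favoured in advance for them. Values of genes that a setting removed are not counted, and 1364 of 1645 were left with that filter. Of 15602 values of named genes, 15010 kept direction and side of the threshold, 590 lost the call, 1 gained it and 1 reversed. With libraries left out, 5737 of 7960 kept both, 2201 lost the call and 22 reversed. Of 78 called lists, 15 lost the call in some setting and 30 without some library, and 45 held in all of these. Without some library the median of 30 of the 78 moved by over 1.5 times. With an estimated correlation 0 were called (39 at an unadjusted p under 0.05, limma's camera). The cause was not tested for any of the changes below, and fits that leave libraries out also rest on fewer libraries.

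Which direction held more changed genes turned in some setting in 11 of 25 contrasts (8 with TMM rescaling), and without some library in 8, so that 13 kept it throughout.

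With libraries of the same parent only, changed genes numbered 979, 395 and 2209 in the trap at day 0, 4 and 8. That kept 44.72, 25.78 and 65.06% of its main calls. The change of the trap effect by day 8 held 1165 genes. Counts were 775, 502 and 2318 in the Pali1 knockout and 556, 374 and 1134 in the double knockout. The main fit may thus understate the spread of C129 and trap libraries and call too many genes in the trap. Such a spread was not told apart from the fewer libraries of that fit (12, against 18). With array weights the Pali mutants differed at 388 genes at day 8. The correlation of double knockout and trap effects was -0.236 and -0.378 at day 8 with pseudocounts of 1 and 16, -0.208 at day 0 with the filter at 50, and -0.317, -0.203 and -0.529 at day 0, 4 and 8 over genes called in either. Leaving out a library it ran from -0.175 to -0.142 at day 0, from -0.0723 to -0.0181 at day 4 and from -0.296 to -0.25 at day 8.

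A library left out leaves a group with 1 sample, assumed to vary like the other groups. Counts at day 0, 4 and 8 then ran from 315 to 491, 150 to 298 and 946 to 1501 in the Pali1 knockout, from 260 to 423, 80 to 232 and 308 to 764 in the double knockout, and from 805 to 1543, 402 to 1174 and 1682 to 2821 in the trap. Between the Pali mutants they ran from 94 to 398, 62 to 158 and 102 to 134, and between the wild types from 1830 to 2630, 1150 to 2081 and 1442 to 2605. For the change of effect by day 8 they ran from 240 to 822, 44 to 304 and 1348 to 2538 in the Pali1 knockout, double knockout and trap. For the double knockout against the trap effect they ran from 1272 to 1841 at day 0 and 463 to 964 at day 4.

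Directions reversed for values of genes not called, and the medians of 2 called lists turned, on the log2 scale. T in C129 at day 8 was 0.15 with a pseudocount of 16, against -0.16, and ran from -1.91 to 1.60 with libraries left out. T ran from -0.75 to 2.04 in C129 at day 4 and -1.25 to 0.63 in Pali at day 8. Sox17 at day 4 ran from -0.12 to 1.82 in C129 and -0.89 to 1.92 in Pali. Pax6 ran from -0.24 to 1.21 in C129 at day 4, and from -0.41 to 0.73 and -0.076 to 1.06 in Pali at day 4 and 8. Hoxb1 in C129 at day 8 ran from -0.14 to 0.34. Lcor ran from -0.21 to 0.56 and -0.81 to 0.23 in the Pali1 knockout at day 0 and 4, and from -0.20 to 0.23, -0.84 to 0.21 and -0.15 to 0.34 in the double knockout at day 0, 4 and 8. The called list of extraembryonic endoderm in the double knockout at day 8 ran from -0.996 to 0.37, and was 0.083 without discordant genes. That of primed epiblast in the double knockout at day 0 was -0.11 without Pali wild type replicate 1, against 0.32.

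The labels give no shared day or batch for the replicate number, but 175 genes differed with it in common over the 15 groups. Deviations of same-numbered libraries correlated at -0.0785 to 0.109 over 105 pairs of groups. Leaving out 1 library ends the balance of the numbers in its group. A replicate block multiplied the 25 counts by 1.03 to 1.41. It ended 15 of the calls of named genes, among 1645 values, and 1 list call, endoderm in the double knockout at day 4 (adjusted p = 0.0502). The planned count models were not run, since whole reads were not recovered. Depth limits the genes near a value of 10, where 1 read is a large share of the value.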

Other observations

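The test of the replicate number was chosen after the values of Xkrx and Eif2s3y had been seen. Genes of the normal course were called as lists in the mutants in 6 of 9 planned tests of rising genes and 6 of 9 of falling genes, not all in 1 direction and none with an estimated correlation. Of 2335 genes that rose to day 8 in C129 wild type, 578 were higher and 39 lower in the Pali1 knockout at day 8 (704 and 63 adjusted over the list alone), with a median of 0.54 and adjusted p = 1.52e-16, or adjusted p = 0.0906 with an estimated correlation. Of 1455 genes that rose in Pali wild type, 556 were lower and 68 higher in the Aebp2 gene trap at day 8 (644 and 95 adjusted over the list alone), with a median of -0.78 and adjusted p = 2.59e-15, or adjusted p = 0.0965 with an estimated correlation.

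Of 1804 genes that fell in C129 wild type 171 were higher and 49 lower in the Pali1 knockout at day 0 (252 and 78 adjusted over the list alone), with a median of 0.18 and adjusted p = 0.000675, or adjusted p = 0.446 with an estimated correlation. Of 1804 genes that fell in C129 wild type 348 were lower and 56 higher in the Pali1 knockout at day 8 (392 and 71 adjusted over the list alone), with a median of -0.20 and adjusted p = 1.21e-07, or adjusted p = 0.242 with an estimated correlation. Of 2335 genes that rose in C129 wild type 231 were higher and 11 lower in the double knockout at day 0 (331 and 16 adjusted over the list alone), with a median of 0.24 and adjusted p = 6.92e-08, or adjusted p = 0.246 with an estimated correlation. Of 2335 genes that rose in C129 wild type 80 were higher and 11 lower in the double knockout at day 4 (118 and 17 adjusted over the list alone), with a median of 0.22 and adjusted p = 6.92e-08, or adjusted p = 0.246 with an estimated correlation. Of 2335 genes that rose in C129 wild type 289 were higher and 26 lower in the double knockout at day 8 (414 and 39 adjusted over the list alone), with a median of 0.37 and adjusted p = 1.53e-09, or adjusted p = 0.224 with an estimated correlation. Of 1804 genes that fell in C129 wild type 74 were lower and 21 higher in the double knockout at day 4 (130 and 44 adjusted over the list alone), with a median of -0.062 and adjusted p = 0.00892, or adjusted p = 0.535 with an estimated correlation. The falling call there was lost without double knockout replicate 2 (median of -0.032, adjusted p = 0.138). The falling median there was -0.095 without Pali wild type replicate 2 and -0.11 without double knockout replicate 1. Of 1804 genes that fell in C129 wild type 148 were lower and 65 higher in the double knockout at day 8 (178 and 85 adjusted over the list alone), with a median of -0.062 and adjusted p = 0.00658, or adjusted p = 0.518 with an estimated correlation. The falling call there was lost without Pali wild type replicate 1 (median of -0.031, adjusted p = 0.089) and without double knockout replicate 2 (median of -0.026, adjusted p = 0.0947). The falling median there was -0.098 without Pali wild type replicate 2. Of 1455 genes that rose in Pali wild type 227 were lower and 44 higher in the gene trap at day 0 (252 and 53 adjusted over the list alone), with a median of -0.35 and adjusted p = 0.000242, or adjusted p = 0.446 with an estimated correlation. The rising call there was lost without gene trap replicate 2 (median of -0.17, adjusted p = 0.139). The rising median there was -0.53 without gene trap replicate 1. Of 428 genes that fell in Pali wild type 77 were lower and 19 higher in the gene trap at day 4 (110 and 32 adjusted over the list alone), with a median of -0.34 and adjusted p = 4.52e-05, or adjusted p = 0.251 with an estimated correlation. The falling median there was -0.23 without C129 wild type replicate 1. Of 428 genes that fell in Pali wild type 136 were higher and 22 lower in the gene trap at day 8 (155 and 26 adjusted over the list alone), with a median of 0.51 and adjusted p = 2.61e-10, or adjusted p = 0.0906 with an estimated correlation.

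Of 20 p53 targets 8 were higher and 1, Pmaip1, was lower in the Pali1 knockout at day 8 (8 and 1 adjusted over the list alone), with a median of 0.21 and adjusted p = 0.0282, or adjusted p = 0.354 with an estimated correlation. That call was lost without Pali wild type replicate 1 (adjusted p = 0.107) or knockout replicate 1 (adjusted p = 0.074). Pmaip1, which promotes cell death, was 296 ± 17.9 in the Pali1 knockout and 1688 ± 500 in Pali wild type at day 8 (adjusted p = 4.31e-05), and rose in the trap from 133 ± 13.1 to 586 ± 5.70 (adjusted p = 6.65e-05), where the list was not called (adjusted p = 0.68).

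The Y-linked gene Eif2s3y lay between 140.5 and 465 in the 12 C129 and trap libraries and at 0 in the 18 Pali libraries, and was higher in replicate 1 in 6 of 6 C129 and trap groups. Xkrx ran from 49.8 to 131566 over the 30 libraries and was higher in replicate 1 in 12 of 15 groups. A difference between the replicate numbers common to all 15 groups was then fitted across all tested genes with limma, and 175 genes passed, 90 higher in replicate 2 and 85 in replicate 1. Of 100 splits with the numbers swapped within groups, the real one included, 1 gave as many genes, and the highest of the others was 2. This argues against chance but, with 100 splits and a test chosen after 2 genes were seen, cannot exclude it. Every histone gene with a symbol starting in Hist among the 175 was higher in replicate 2, such as Hist1h2ad (log2 difference of 0.399, adjusted p = 0.00797). The course genes Zfp42 (-0.36, adjusted p = 0.027) and Pax6 (0.648, adjusted p = 0.0422) were also among the 175. The cause was not tested. Xkrx (log2 difference of -3.65, adjusted p = 0.0873) and Eif2s3y (-0.376, adjusted p = 0.215, with 9 groups at 0) did not pass. What the number stands for is not given in the labels, and each group holds 1 library of each number.

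Tmsb4x was listed at 0 in both libraries of 5 groups, the Pali1 knockout and C129 wild type at day 0 and 4 and the trap at day 4. It lay at 340.03 or more in the other libraries, and its values of 0 can be failed estimates.

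Genes with duplicates more than 8-fold apart may reflect isoforms whose reads are missing from the gene value, a hypothesis tested with annotated transcripts. Of 1139 such genes with a transcript count, 62.42% had 2 or more transcripts, against 41.5 to 47.3% (central 95%) in 10000 expression-matched sets. Single genes were not tested, and no biological explanation was tested.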
